A study of Drosophila melanogaster with 27 samples.

How the data were processed

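The series used CUT&RUN, in which an antibody directs micrococcal nuclease to chromatin and the released fragments are sequenced, with an antibody against monomethylated lysine 20 of histone H4 (H4K20me1). Per the labels, each library came from 20 wing imaginal discs of female wandering Drosophila melanogaster larvae of instar 3, raised at 25 °C, and 27 libraries fall into 10 groups. Groups were read from the titles and genotypes in the labels. The labels do not say whether libraries of a group came from separate animals or days, beyond the number of discs in each.

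The analysis rests on 1 processed file, the authors' deposited peak list for Oregon-R discs, in which H4K20me1 antibody libraries (n = 3) were set against libraries without primary antibody (n = 3), per the labels. It holds the chromosome, start, end and width of each peak, in base pairs, and no score, fold, p-value or value per library. For all peaks the width equalled end minus start plus 1, so positions count from 1 with both ends included, and all boundaries lay on a 50 bp grid. The genome build is dm6, per the submitters' processing notes, which also name Bowtie2, SAMtools, bedtools, edgeR and deepTools without versions or roles. The peak caller, its threshold, any filter or merging of peaks and any pooling of replicates are not given in the sources used here. Read depth per library is therefore unknown, as is the strength of each peak, and a gene without a peak may carry signal below the authors' threshold. No fit with a replicate block, no omission of a replicate and no comparison between genotypes can be made from a single list. Values for the other 8 groups (21 libraries) were not analysed here.

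Genes came from the NCBI RefSeq gene table of the Release 6 assembly, the same build, which gives coordinates, symbols and biotypes but no strand, exons or sequence. A gene had a peak when a peak overlapped its body by at least 1 bp. Tests used the 13922 protein-coding genes on 2L, 2R, 3L, 3R, X and 4. Arm spans ran to the last gene or peak, since chromosome lengths were not used. The covered share of X was compared with that of the 4 large autosome arms in 1 Mb bins by a permutation test (100000 permutations). The share of peak bp in gene bodies was compared with 10000 circular shifts of the peaks along their arm. The number of members of 22 gene lists with a peak was compared with random genes of the same length decile by an exact test that convolves hypergeometric distributions, two-sided by doubling, with Benjamini-Hochberg adjustment over the 22 lists and a threshold of 0.05. Peak coverage of the middle 50% of gene bodies was compared with that of the outer 25% at each end by a sign-flip permutation test (100000 permutations) over protein-coding genes of at least 2 kb with a peak that overlap no other protein-coding gene. All tests were two-sided. Intervals of shares are 95% Wilson intervals. They and the p-values treat genes, bins or shifts as the unit, cover chance in the choice of genes only, and do not measure the spread between libraries; neighbouring genes and bins are not independent. A share of 0 is given with the limit that 3 counts of the total set.

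The groups, lists, tests and a first set of other settings were fixed before the data were examined. Named genes follow a rule fixed at the same time. It took Set8, Hmt4-20, l(3)mbt, His4r and the replication-dependent histone genes; the genes under the 10 widest peaks; the 10 genes of at least 2 kb with the most covered bp; and, in each list with adjusted p under 0.05, the 4 members with the largest covered share and the 2 longest members without a peak (in other lists, 2 and 1). A gene that the rule takes is not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Some names in the lists are older symbols and were read as Delta, dachs, nanos, Polr2A, Sirt1 and Su(var)3-3, and no member was found for Caska or for the Pcp prefix. The replication-dependent histone genes were described apart from the lists because they are repeated.

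Planned tests of promoters, untranslated regions, exons and introns, of GC content, and of 5′ against 3′ parts of genes were not run, since they need exons, sequence or strand. The comparison of the middle with the outer parts of genes took the place of the last and was chosen after the file was seen. So were the biotype, symbol-family and chromosome 4 comparisons, and the alternatives named as such in the closing section. The other settings fixed beforehand were the wider 50% of the peaks, other overlap rules, other length matching, each large arm left out, other bin sizes and measures, and all annotated genes.

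Before use, the tests were run on simulated data, in which genes, peaks and bins were drawn independently of their neighbours. With no effect, the list test called 1.5% of 200 simulated lists at an unadjusted p of 0.05, 37% at an odds ratio of 2, 91.5% at an odds ratio of 4 and 63% at an odds ratio of 0.25, so moderate differences can be missed. The circular shift test called 7% of 100 simulations with random peaks and 70% when 20% of peaks were moved onto genes. The bin test called 6% of 100 simulations without a difference and 98% with a shift of 1 SD, and the sign-flip test 4% without a shift and 100% with 0.1 SD. Clustered genes, shared peaks and neighbouring bins that resemble each other were not simulated. The rates of false calls in the real data may therefore be higher. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.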

Results

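The study asked how mutation of Set8, the H4K20 monomethyltransferase, or of H4K20 itself changes H4K20me1 across the genome of the wing disc, the larval epithelium that forms the adult wing and notum. Oregon-R wild-type discs were profiled with H4K20me1 antibody (n = 3) and without primary antibody (n = 3). The other antibody libraries came from Set8 null discs (n = 3), from Set8 null discs with a wild-type (n = 3) or catalytically mutated (n = 3) Set8 transgene, and from discs lacking the histone gene complex. The last carried a 12-copy histone array with wild-type H4 (n = 2), H4K20A (n = 2) or H4K20R (n = 3), or, in a His4r null background, with wild-type H4 (n = 3) or H4K20R (n = 2). What follows describes where H4K20me1 peaks lay in Oregon-R discs. The mutant groups were not analysed here, and depth per library is unknown.

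The authors' list held 6914 peaks that covered 17.5 Mb. Peaks were mostly short, with a median width of 1100 bp (quartiles 250 and 3050 bp), but ranged from 150 to 68600 bp. The narrowest width was shared by 1057 peaks (15.3%), whereas the 328 peaks of 10 kb or more held 30.5% of the covered sequence. The smallest gap between neighbouring peaks was 1050 bp.

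Peaks covered 12.4% of 2L, 14.3% of 2R, 12.6% of 3L, 13.3% of 3R and 12.8% of X, and 14.4% of the small chromosome 4. Among the large arms, the share of protein-coding genes with a peak was lowest on 2L, at 33.1% (95% CI 31.3 to 34.9). It was highest on X, at 42.1% (95% CI 40.0 to 44.1), and 2R, at 41.0% (95% CI 39.2 to 42.9). It was 38.0% (95% CI 36.2 to 39.9) on 3L and 37.6% (95% CI 36.0 to 39.3) on 3R, and differences between arms in this share were not tested. Bins next to the centromere on 2R, 3L and 3R were nearly free of peaks, with at most 0.05% covered in each of the first 3 bins of 3R. In these female discs, which hold the same number of X chromosomes and autosome sets, 1 Mb bins of X were covered to 13.1% ± 6.51 (SD, 23 bins) and those of the autosome arms to 13.2% ± 7.34 (SD, 108 bins). The difference of -0.0790 points was far smaller than the spread between bins (permutation p = 0.962). Its sign turned to 1.09 points in 5 Mb bins and to 5.24 peaks per Mb when peaks were counted (permutation p = 0.685 and 0.345). Restricted to bins of at least 20 protein-coding genes, a setting chosen after the data were seen, X stood at 13.1% ± 6.51 (SD, 23 bins) and the autosomes at 15.03% ± 5.94 (SD, 94 bins), a difference of -1.93 points that was not significant (permutation p = 0.173).

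**Figure D1:**
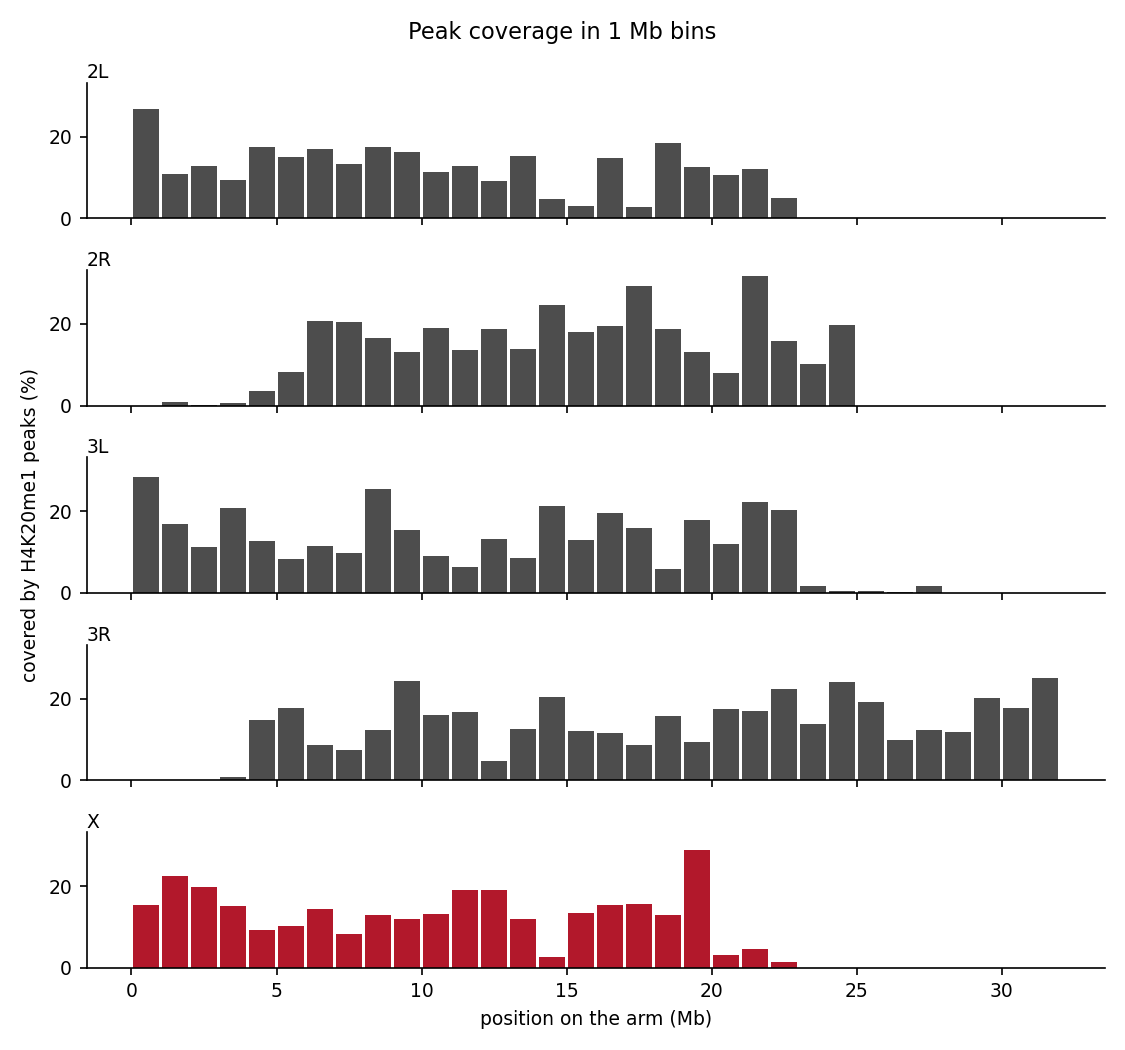
Share of each 1 Mb bin covered by H4K20me1 peaks (y axis, %) along the 5 large arms (x axis, Mb), X in red and autosome arms in grey. Mean coverage was 13.1% on X and 13.2% on the autosome arms, and bins near the centromere of 2R, 3L and 3R were nearly empty.

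H4K20me1 peaks lay almost entirely within genes. Of the covered sequence, 97.7% fell in protein-coding gene bodies, against 67.4% ± 1.44 (SD of 10000 shifts) when the peaks were shifted along their arms (circular permutation p = 0.0001, the smallest these shifts can give). Shifts of only 50 to 500 kb, added after the data were seen, left 71.5% ± 1.00 in genes (permutation p = 0.0001, again the smallest). At least 1 protein-coding gene was overlapped by 6799 peaks (98.3%, 95% CI 98.0 to 98.6), at least 2 by 1682 peaks and at least 5 by 30 peaks.

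The widest peak, at 2L 18320151 to 18388750 (68.6 kb), covered 93.5% of Fas3, which encodes a homophilic adhesion protein of septate junctions, together with Acp36DE and CG34171, which lie inside it. Next came peaks over klar, a gene of nuclear positioning (56.3 kb), dally, a glypican of the Wingless and Dpp pathways (51.2 kb, reaching 55 bp into Mcm7), and kek5 (47.0 kb). A 44.6 kb peak on 2R lay within the planar polarity gene pk and covered the serpin genes Spn43Ab, Spn43Ad and nec and 4 CG-numbered genes nested there. The remaining wide peaks lay over ed, heca, heph, mub and Sema2b, the last with Menl-1 and Menl-2. By total covered sequence, the teneurin gene Ten-m led with 109907 bp (95.7% of the gene), followed by kek5, SKIP, heph, klar, mbl, heca, Mur2B, Ten-a and ed, of which Ten-a was covered to 27.1% and ed to 91.0%. Of the 80438 bp covered in Mur2B, 76519 bp (95.1%) lie in br, which is nested within it, so the place of Mur2B in this order rests almost wholly on br.

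**Figure D2:**
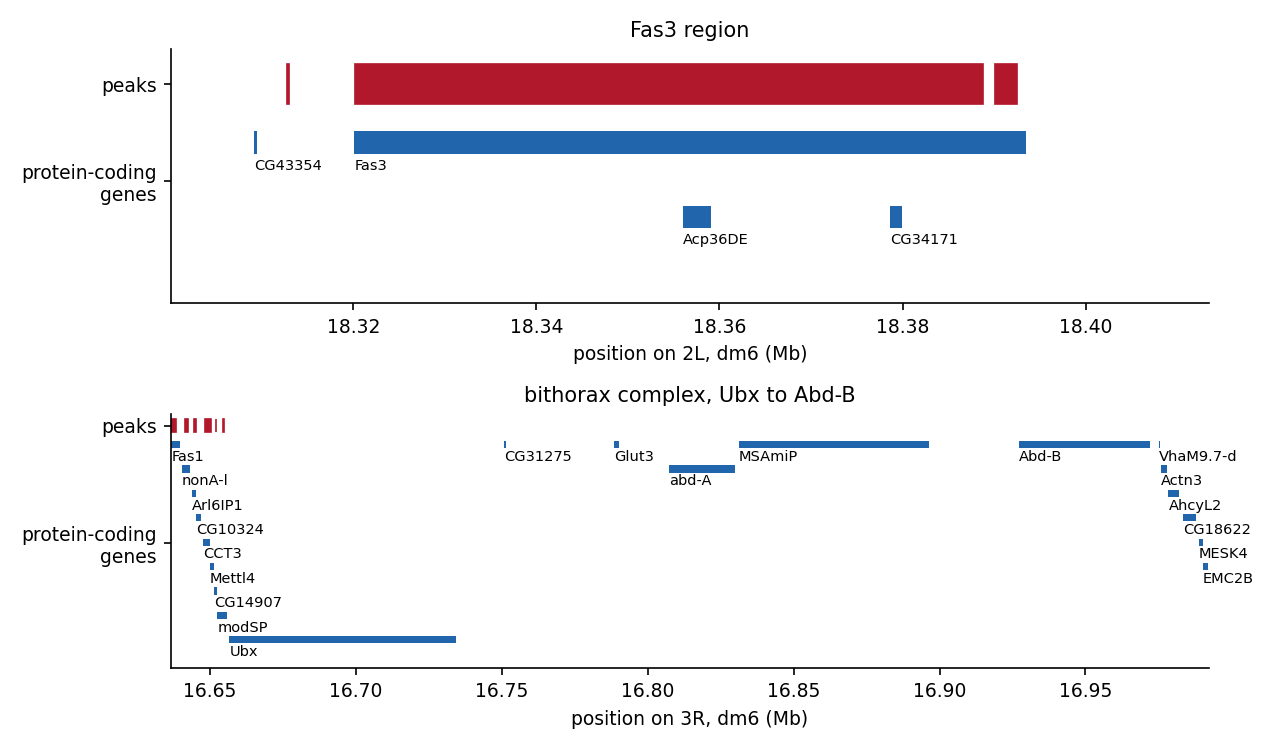
Maps of 2 regions in dm6 coordinates (x axis, Mb), with H4K20me1 peaks in red and protein-coding genes in blue. A 68.6 kb peak covers 93.5% of Fas3 on 2L, whereas no peak lies in the 316 kb from Ubx to Abd-B on 3R.

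Along genes, coverage was highest in the interior and fell towards both ends. In 1972 protein-coding genes of at least 2 kb that carried a peak and overlapped no other such gene, the middle 50% of the body was covered to 55.0% and the outer 25% at each end to 42.5%. The difference was 12.5 ± 0.658 points (SE over genes), with the middle higher in 1214 genes and lower in 642 (permutation p = 1e-05, the smallest these permutations can give). Coverage was 31.9% and 30.9% in the terminal 5% of the body on either side, and 25.9% and 25.7% over the 5 kb of flanking sequence. The genes were chosen for a peak in the body, so lower coverage of the flanks follows in part from this choice. Strand was not used, so starts and ends of genes are not told apart here.

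**Figure D3:**
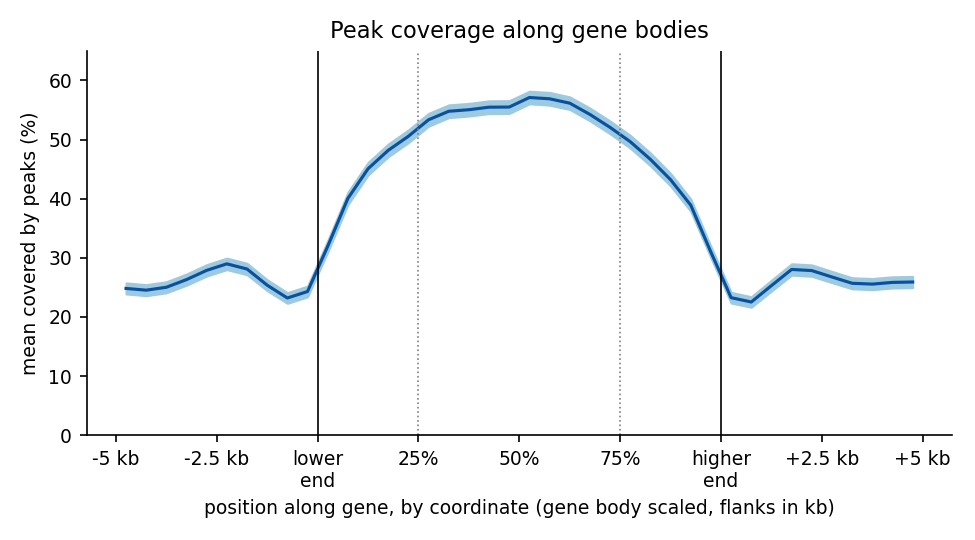
Mean share covered by peaks (y axis, %; band, SE over 1972 genes) along gene bodies scaled to the same length and 5 kb on each side (x axis), in coordinate order. Coverage rises from 31.9% and 30.9% in the terminal bins to 57.1% near the middle. All genes were chosen for a peak in the body, so the flanks are lower in part by this choice.

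Of 13922 protein-coding genes, 5339 had a peak (38.3%, 95% CI 37.5 to 39.2), 2550 were covered over at least 50% of their body and 971 over at least 90%. Long genes had peaks more often than short ones, as a rule of 1 bp of overlap favours. The share rose from 11.7% (95% CI 10.1 to 13.5) in the shortest decile, with a median length of 567 bp, to 57.1% (95% CI 54.5 to 59.7) in the ninth, with a median of 9160 bp, and was 51.9% (95% CI 49.2 to 54.5) in the longest. The median covered share of the genes with a peak was 100% in the shortest decile, 48.9% in the ninth and 29.6% in the longest. Because 5762 protein-coding genes (41.4%) overlap another one, a peak over a gene cannot always be assigned to that gene.

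**Figure D4:**
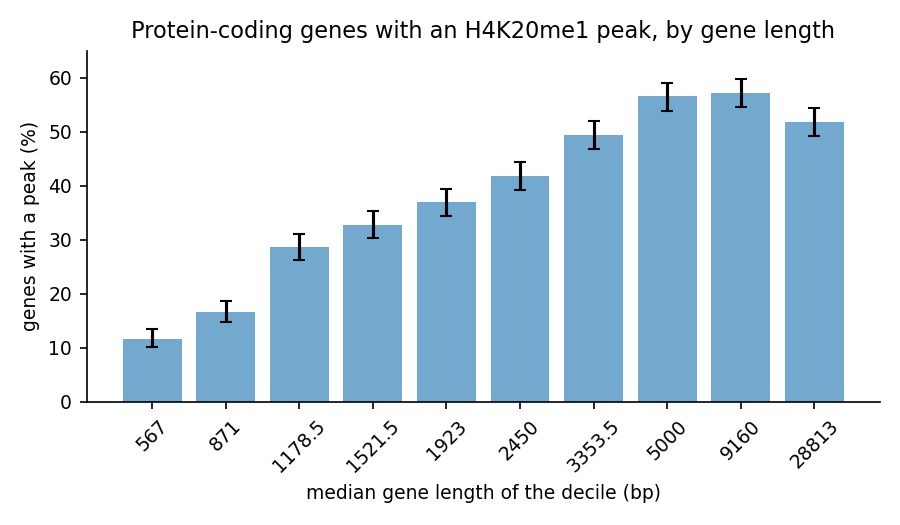
Share of protein-coding genes with an H4K20me1 peak (y axis, %; error bars, 95% Wilson intervals) by decile of gene length (x axis, median length in bp). The share rises from 11.7% to 57.1% and is 51.9% in the longest decile.

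Genes of protein synthesis and turnover carried the mark far more often than genes of equal length. Among cytoplasmic ribosomal protein genes, 80 of 92 had a peak (87.0%, 95% CI 78.6 to 92.4, against 28.9% expected from length; exact test, adjusted p = 1.05e-31), and RpS7, RpS4 and RpL4 were covered completely. RpL7-like and RpL22-like were the longest of the 12 without a peak. Translation initiation and elongation factors had peaks in 40 of 52 genes (76.9%, 95% CI 63.9 to 86.3, against 40.5% expected; exact test, adjusted p = 2.81e-07), with eIF2A, eIF3l, eEF1gamma and eIF3e covered completely and eIF4B and eEF1alpha2 without a peak. Proteasome subunits had peaks in 30 of 48 genes (62.5%, 95% CI 48.4 to 74.8, against 30.4% expected; exact test, adjusted p = 1.53e-05). Rpn1, Rpt5, Rpt2 and Prosbeta2 were fully covered, whereas Prosbeta2R2 and Rpt3R had none. Mitochondrial ribosomal proteins had peaks in 37 of 73 genes (50.7%, 95% CI 39.5 to 61.8, against 21.7% expected; exact test, adjusted p = 1.43e-07), such as mRpS22, mRpL16, mRpL10 and mRpL48, but not mRpS9 or mRpL21. Of these 37 genes, 24 overlap another protein-coding gene, but the call held among genes that overlap no other. It was lost when the peak midpoint had to lie in the gene and without length matching (exact test, adjusted p between 1.14e-10 and 0.967 over 20 alternatives). Cytoskeletal and housekeeping genes had peaks in 18 of 19 cases (94.7%, 95% CI 75.4 to 99.1, against 48.6% expected; exact test, adjusted p = 8.19e-05), including Hsc70-4, the RNA polymerase II subunit gene Polr2A, the myosin II gene zip and Act42A. Gapdh1 was the exception. This call was lost under the midpoint rule, where the adjusted p of the exact test was highest (range 2.41e-06 to 0.0672).

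Genes of the cell cycle, the Hippo pathway and chromatin regulation were also marked more often than genes of equal length. Cell cycle and replication genes had peaks in 32 of 36 cases (88.9%, 95% CI 74.7 to 95.6, against 44.9% expected; exact test, adjusted p = 2.38e-07). Among these, aurB was covered completely, CycB to 88.4%, Dp to 80.6% and Rbf to 79.2%, and Mcm5 and Cdc6 had no peak. The call was lost when at least 50% of the gene had to be covered (exact test, adjusted p between 4.61e-09 and 0.343 over 20 alternatives). In the Hippo growth pathway, 14 of 16 genes had a peak (87.5%, 95% CI 64.0 to 96.5, against 49.5% expected; exact test, adjusted p = 0.00701). The atypical cadherin gene ft was covered to 96.8%, crb to 90.4%, ex to 81.6% and the kinase gene wts to 78.3%, and sav and mats were without a peak. Chromatin regulators had peaks in 28 of 31 genes (90.3%, 95% CI 75.1 to 96.7, against 52.3% expected; exact test, adjusted p = 3.15e-05), led by Su(var)3-7, ash1, Scm and Iswi, and not in Su(z)2 or esc.

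Wing patterning genes were marked in 33 of 45 cases (73.3%, 95% CI 59.0 to 84.0, against 51.96% expected; exact test, adjusted p = 0.00886). The beta-catenin gene arm was covered completely, dally to 96.0%, the inhibitory Smad gene Dad to 87.5% and tsh to 85.7%, whereas the transcription factor genes ct and kn had no peak. In the list of the Notch pathway and the E(spl) complex, 13 of 22 genes had a peak (59.1%, 95% CI 38.7 to 76.7, against 35.4% expected; exact test, adjusted p = 0.0351). The gamma-secretase genes Psn, pen-2 and aph-1 were covered completely and mib1 to 90.3%, while neur and E(spl)m3-HLH had none. Of the 9 E(spl) genes only E(spl)mbeta-HLH, named after its value was seen, had a peak, against 12 of the 13 other members. The call for this list was lost in 9 of 20 alternatives (exact test, adjusted p between 0.000688 and 0.175), and 4 of its members are also in the wing list.

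Hox genes and other classical Polycomb targets had peaks less often than length-matched genes, in 7 of 31 cases (22.6%, 95% CI 11.4 to 39.8, against 51.3% expected; exact test, adjusted p = 0.00412). The paired Polycomb-group genes ph-d and ph-p were covered to 99.5% and 50.1%, inv to 56.1% and bi to 9.41%. No peak lay in Ubx (3R 16656623 to 16734426) or Abd-B (3R 16927212 to 16972236), nor anywhere in the 316 kb between their outer ends. Of all windows of that length on the large arms, taken every 10 kb, 5.17% were free of peaks. These windows include the nearly empty stretches next to the centromeres, and the share elsewhere was not computed. The call for the list was lost in 3 of 20 alternatives (exact test, adjusted p between 0.000258 and 0.269). These were the ones without length matching, with at least 50% coverage, and without arm 3R, which holds Ubx and Abd-B. Leaving out 3R removes other members too, so fewer genes were then tested. The deficit was not called for the members on the other arms alone. The share stayed below expectation in all 20 alternatives (-36.6 to -10.9 points).

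Genes of sensory reception, cuticle, eggshell and digestion were almost devoid of peaks. Odorant, gustatory and ionotropic receptor genes had a peak in 9 of 179 cases (5.03%, 95% CI 2.67 to 9.28, against 36.5% expected; exact test, adjusted p = 4.71e-23). Those most covered, Gr43a, Ir51b, Or43b and Gr77a, each overlap another protein-coding gene, as do 5 of the 9. The longest receptor genes without a peak were Ir41a and Ir40a. Among cuticle proteins, 1 of 92 genes had a peak (1.09%, 95% CI 0.192 to 5.90, against 25.3% expected; exact test, adjusted p = 1.49e-10), namely Cpr73D, covered to 4.24%, and Cpr50Ca and Cpr50Cb had none. No peak was found in 25 serine protease genes of the Jonah and trypsin families, which allows a share of up to 12% (19.2% expected; exact test, adjusted p = 0.0121), with Jon44E and Jon99Ciii the longest. Chorion, vitelline and yolk genes had a peak in 1 of 19 cases (5.26%, 95% CI 0.935 to 24.6, against 26.8% expected; exact test, adjusted p = 0.0387). That gene, Cp190, encodes a centrosomal and insulator protein and entered the list by its symbol, as did Cp110, which had no peak, like the chorion gene Cp7Fb. Without Cp190 and Cp110, a setting chosen after the data were seen, 0 of 17 genes had a peak. This allows a share of up to 17.6%, against 23.3% expected (exact test, adjusted p = 0.0233). The protease call was lost in 8 of 20 alternatives (exact test, adjusted p up to 0.373, from 2.70e-05) and the chorion call in 12 of 21 (exact test, adjusted p up to 0.912, from 0.00477).

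Markers of neurons, muscle, hemocytes and fat body, cell types that a dissected disc can hold, were also marked less often than genes of equal length. Neuron markers had peaks in 3 of 17 genes (17.6%, 95% CI 6.19 to 41.0, against 53.1% expected; exact test, adjusted p = 0.00927). These were Syx1A, covered to 68.5%, elav to 26.1% and unc-13 to 0.337%, and the ion channel genes Sh and para had none. Muscle markers had peaks in 4 of 21 genes (19.0%, 95% CI 7.67 to 40.0, against 50.03% expected; exact test, adjusted p = 0.00970). The RNA-binding protein gene how was covered to 71.9% and Tm1 to 41.9%, but Mef2 and twi only to 3.53% and 0.477%, and sls and bt had no peak. Hemocyte and fat body markers had peaks in 2 of 16 genes (12.5%, 95% CI 3.498 to 36.0, against 48.2% expected; exact test, adjusted p = 0.00927), crq, which overlaps ex and was covered to 86.9%, and Mtp, covered to 3.97%. Pxn and srp had none. Calls were lost in 5 of 20 alternatives for neuron markers and in 3 each for muscle and hemocyte markers (exact test, highest adjusted p 0.329, 0.160 and 0.288, lowest 0.00336, 0.00378 and 0.00336). Tracheal markers, with peaks in 7 of 10 genes, did not pass the threshold (70.0%, 95% CI 39.7 to 89.2, against 52.8% expected; exact test, adjusted p = 0.464), among them pio and esg but not bnl.

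**Figure D5:**
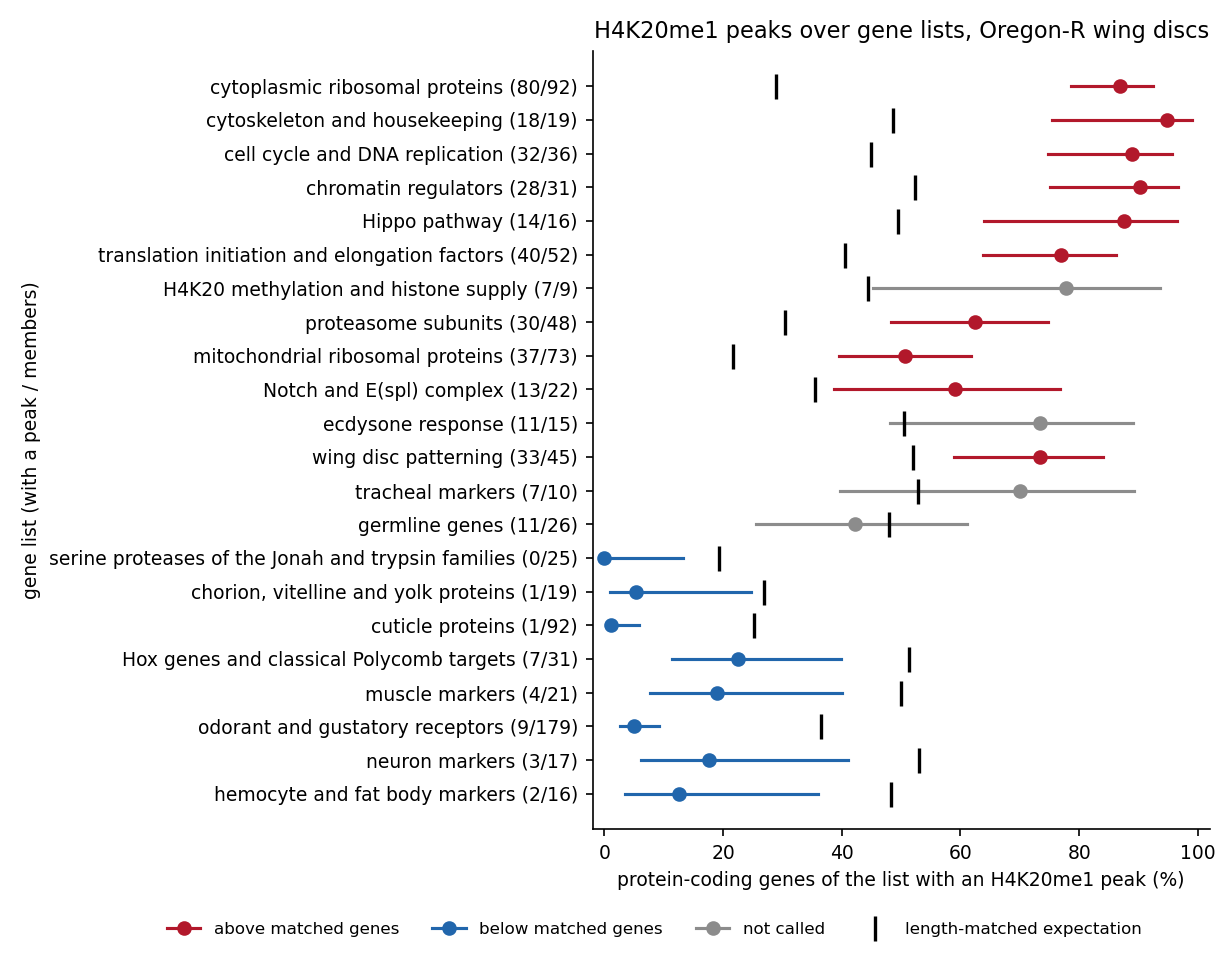
Share of each list's genes with an H4K20me1 peak (x axis, %; points with 95% Wilson intervals) for the 22 gene lists (y axis), with the share expected for genes of the same length as black ticks. In red are 10 lists above and in blue 8 lists below that expectation at an adjusted p under 0.05, with shares from 0 of 25 protease genes to 94.7% of cytoskeletal and housekeeping genes.

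Among the genes of H4K20 methylation, Set8, Hmt4-20 and l(3)mbt had peaks, but the list that holds them did not pass the threshold. A single peak covered 85.1% of Set8 (3R 14316038 to 14320494) and another 86.3% of Hmt4-20 (X 648483 to 656033), the di- and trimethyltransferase. In l(3)mbt (3R 27266326 to 27273273), whose product binds methylated histone tails, 2 peaks covered 46.1%. Each of these genes overlaps another protein-coding gene. His4r, the single-copy H4 gene, had no peak. The list of these genes with histone variants and histone supply factors had peaks in 7 of 9 genes (44.5% expected; exact test, adjusted p = 0.0866), including His3.3A, covered to 96.1%, and not Slbp. It passed the threshold when the peak midpoint had to lie in the gene (exact test, adjusted p between 0.0162 and 0.433 over 20 alternatives). In the cluster of 111 replication-dependent histone genes on 2L (21416953 to 21541681), 3 genes had a peak, His3:CG33842, His1:CG33864 and His2B:CG33868, and 4 peaks covered 1800 bp. These genes are near-identical copies that share reads, so the values there are uncertain.

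Lists of ecdysone response genes and germline genes did not pass the threshold against length-matched genes. Ecdysone response genes had peaks in 11 of 15 cases (50.5% expected; exact test, adjusted p = 0.139), including br, covered to 85.3%, and Hr78, covered to 84.3%, but not Eip93F. Without length matching this list passed the threshold (exact test, adjusted p between 0.0217 and 1 over 20 alternatives). Germline genes had peaks in 11 of 26 cases (47.9% expected; exact test, adjusted p = 0.704). The most covered, grk and zuc, each overlap another gene, and AGO3 had none. On chromosome 4, 45 of 80 protein-coding genes had a peak (56.2%, 95% CI 45.3 to 66.6, against 51.7% expected; exact test, p = 0.478). With matching on gene density as well as length, chosen after the data were seen, 44.4% were expected and the difference passed the threshold (exact test, p = 0.0366).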

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

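For the flagged result below no test was run, so none was chosen after it was seen. Peaks were found on the Y chromosome although the discs are labelled female. There were 2 such peaks, at Y 995801 to 995950 and Y 3504301 to 3504450, each 150 bp wide, the narrowest width in the list, and neither overlapped an annotated gene. They were singled out because they lie in sequence that no comparison uses. No explanation was tested, since sequence shared between the Y and other chromosomes was not analysed here.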

How the results depend on the processing

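Chosen after the data were seen were joining at 2 kb, leaving out the narrowest peaks, local shifts, bins chosen or permuted by gene content, windows of 500 bp on both sides of genes, non-overlapping genes, clusters, density and flank matching, the chorion list without Cp110 and Cp190, and all settings for the middle of genes. Tests of promoters, exons, GC content and 5′ against 3′ parts were not run with any alternative, and joining peaks 1 kb or less apart changes nothing, since no gap is that small. No paired analysis was possible because the peak list has no values per library. The excess of peaks in gene bodies (26.2 to 31.5 points) and in the middle of genes (9.83 to 15.5 points) kept direction and call under all alternatives run.

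By construction, the wider 50% of peaks numbered 3472 with a median of 3050 bp, and joining at 2 kb left 4197 peaks with a median of 2450 bp. At least 50% coverage left 2550 marked genes. In the bin tests X and autosomes never differed past the threshold. The sign turned to 0.116 points with joining at 2 kb, 1.09 points in 5 Mb bins and 5.24 peaks per Mb, and the cause was not tested. The share of genes with a peak, which was highest on X among the large arms, was not tested.

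Of 22 lists, 18 passed the main test, 8 of them below expectation. With at least 50% coverage 11 passed, 2 of them below; fewer genes then count as marked, so a deficit is harder to reach. The lists below numbered 4 without length matching, 4 without arm 3L and 5 among non-overlapping genes. Without length matching, the lists lost were neuron, muscle, hemocyte and fat body markers and Hox genes. The share expected for each of these is higher with length matching. The other settings test fewer genes, but the cause of the lost calls was not tested. Cytoplasmic ribosomal proteins, translation factors, proteasome, chromatin regulators, Hippo, wing, receptors and cuticle passed under all list alternatives run. Among lists, the sign turned only in those that passed under no setting. Germline genes turned to 2.18 points with the wider peaks, 5.47 with 500 bp windows, 3.96 without length matching and 4.48 without arm 3R, and tracheal markers to -1.63 with at least 50% coverage; the cause was not tested. Depth, unknown here, limits what the absence of a peak shows.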

Other observations

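The comparisons in the first and second paragraphs were chosen after the data were seen. The predictions of the tests that follow were written before their results were seen. The further values given for the genes named -like, R or T were added afterwards. Among non-coding genes, small nucleolar RNA genes stood out. A peak lay over 213 of 269 snoRNA genes (79.2%, 95% CI 73.9 to 83.6), on 71 separate peaks. Of the snoRNA genes that overlap a protein-coding gene 84.0% had a peak, against 26.8% of miRNA genes that overlap one. The difference was 57.3 points (Fisher's exact test, p = 1.20e-30). For tRNA genes that overlap one the share was 10.4%, a difference of 73.6 points (Fisher's exact test, p = 7.84e-45). Where no protein-coding gene was overlapped, 60.7% of snoRNA genes still had a peak, against 9.78% of miRNA genes and 2.11% of long non-coding RNA genes, differences that were not tested. No peak lay over 98 rRNA genes, which allows a share of up to 3.06%. These genes are repeated, so reads from them cannot be placed with certainty. Several snoRNA genes can share a host or a peak, so these genes are not independent, although the p-values treat them as if they were. The overlapped protein-coding genes were not matched on length or kind. Whether the differences only follow the peaks of the overlapped genes was not tested.

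Gene families grouped by symbol partly repeat the lists. Of 94 families with at least 8 members, 35 differed from length-matched genes at an adjusted p under 0.05, 18 above and 17 below, and 27 of these with 1 member per 20 kb cluster. In 11 of the 35, over 50% of the members are in the lists or in the histone gene cluster. The other 24, of 76 such families tested, were 12 above and 12 below, and 17 of them also differed with 1 member per cluster. Peaks lay over 19 of 25 MED genes of the Mediator complex (33.8% expected; exact test, adjusted p = 9.04e-05), 18 of 19 Sec genes of secretion (46.6% expected; exact test, adjusted p = 9.57e-05), 17 of 20 autophagy (Atg) genes (45.6% expected; exact test, adjusted p = 0.00190) and 8 of 8 CCT chaperonin genes (43.97% expected; exact test, adjusted p = 0.00990). At the other end stood the cytochrome P450 (Cyp) genes with 9 of 85 (41.8% expected; exact test, adjusted p = 6.54e-09), Obp odorant-binding protein genes with 1 of 51 (21.3% expected; exact test, adjusted p = 0.000509) and the dpr synaptic immunoglobulin genes with 0 of 21 (a share of up to 14.3%, 53.1% expected; exact test, adjusted p = 2.95e-06). Osi genes had 0 of 25 (a share of up to 12%, 36.9% expected; exact test, adjusted p = 9.57e-05), but with 1 member per cluster their 5 clusters did not differ (exact test, adjusted p = 0.485). Genes known only by a CG number had peaks in 25.2% of 6097 cases, against 33.9% expected from length (exact test, p = 1.52e-92). The other 7825 genes had peaks in 48.6% of cases. Members of the lists and families carry names, and the tests did not match on this. A part of each excess may therefore reflect named against unnamed genes.

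The 5 lists of ribosomal, proteasome, translation and housekeeping genes, 283 genes together, carried peaks 41.4 points more often than length-matched genes. Crowding by close neighbours was not the whole cause, as matching also on the number of genes within 25 kb left 39.8 points (exact test, p = 3.58e-49). Matching on the covered share of the 10 kb on each side left 31.1 points (exact test, p = 6.06e-36). For the 5 lists together, marked surroundings so measured may account for a part of the excess but not for all of it. When the peak midpoint had to lie in the gene, the mitochondrial ribosomal and the housekeeping lists lost their calls. Both lists kept their calls with matching on the covered share of the 10 kb on each side. The settings differ in outcome, so for these lists peaks that reach in stay open as a cause. GC content was not tested. The design has no group with other expression of these genes, so no biological explanation was tested.

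The 4 lists of receptors, cuticle, eggshell and proteases, 315 genes together, fell by 27.8 points below length-matched genes. For the 4 lists together, counting clustered paralogs many times is not the whole cause. With 1 member per 20 kb cluster, the longest, the difference was -30.8 points (exact test, p = 6.93e-23). Taken alone in this way, the chorion and protease lists lost their calls, so for them this cause stays open. Both also lost their calls with matching on the covered share of the 10 kb on each side. Unmarked surroundings therefore stay open for them as well, and that matching was not run for the 4 lists together. Matching on gene density left -25.5 points (exact test, p = 7.63e-35). Reads shared between paralogs, which could hide peaks, were not tested for lack of sequence and stay open. No biological explanation was tested.

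In the ribosomal, proteasome and translation lists, the members without a peak were tested for having names given to extra copies of other members. Such genes are called copies here by name only, and a -like gene need not be a duplicate. The names end in -like or, in the proteasome, in R or T after the subunit name, with or without a number behind it. Of 21 such copies 20 had no peak, against 58 of 244 other members, a difference of 71.5 points (Fisher's exact test, p = 5.60e-11). The exception, named after its value was seen, was RpLP0-like. Against genes of the same length, 26.8% of the copies would be expected to have a peak, more than the 1 found (exact test, p = 0.0226). Of the 78 members without a peak 74.4% (95% CI 63.7 to 82.7) are not such copies, but without the mitochondrial ribosomal proteins, where the names mark no copy, 20 copies and 22 of 171 other members lacked a peak, and names can miss further paralogs. Expression was not measured here, no biological explanation was tested, and reads shared between copies stay open.

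For wing patterning genes, membership in the list of Hox genes and Polycomb targets was tested as a reason for the missing peaks. Of the 6 genes in both lists 2 had no peak, against 10 of the other 39, a difference of 7.69 points (Fisher's exact test, p = 0.650), and 83.3% (95% CI 55.2 to 95.3) of the 12 wing genes without a peak were not in the other list. With only 6 genes in both lists, membership could not have accounted for most of the 12, whatever the test gave. The 6 genes are too few to exclude an effect. The list may also leave out Polycomb targets, so the question stays open.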
